A study of Mus musculus with 2 samples.

How the data were processed

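Chromatin from livers of male and female CD-1 mice aged 8 weeks was immunoprecipitated with a rabbit antibody raised against a fragment of CUX2, per the labels' protocols, and sequenced on the Illumina platform. The series holds 1 male and 1 female sample, and the reads of each are called a library here. No input or control antibody library was analysed here. Each library was deposited as a list of mapped 35 base reads, and a single peak list compares the libraries. The genome build is mm9, per the submitters' processing notes. The aligner is not given in the sources used here.

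Peaks were called with MACS, per the file headers, with the female reads as the ChIP file and the male reads as the control file. Per the file headers the settings were a p-value limit of 1e-05, a band width of 150, a model fold range of 10 to 30, local background over 200 and 1000 bp, at most 2 reads kept per position, a fragment model of 135 bp and an effective genome size of 1.87e+09. The version of the caller is not given in the sources used here. The peak list gives a read count per peak, which per the file headers is the number of tags in the region. Its score is the caller's p-value on a negative log scale multiplied by 10, which the authors deposited both as such and with 190 added. Its fold enrichment is the ratio of female reads to the local expectation from male reads, as deposited by the authors. Its false discovery rate is in percent and is the authors' deposited value from the swap of the libraries in the caller. The fifth column of the deposited read lists holds a score of 1000, or 0 in the female lines that carry sequence, with no measurement, and reads were counted as lines. The line totals of 33684897 and 8044595 equal the totals in the header of the peak list.

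The read lists joined parts of different line formats, 4 in the female and 2 in the male file. They were separated by format and named parts A to D and A to B in file order. Female part B carried read sequences and 217 mitochondrial reads, which were left out. Minus-strand starts in part B lay 1 base higher than in the other parts. They were moved by that base where positions were compared between parts and where repeats were removed for ratios, enrichment and windows. They were not moved for the shares of repeated reads, the X shares with 1 read per position and strand, the fragment lengths or the calling of sites from part B alone. The lines used name chromosomes 1 to 19 and X, and the planned share of chromosome Y was not analysed here, since no line names it. Fragment length was estimated by cross-correlation of the strands at 155 bp in the female and 160 bp in the male library. Each read was counted where its 5 prime end, moved downstream by 50% of that length, fell.

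Ratios between libraries are ratios of read counts scaled by all reads on the chromosomes used (RPM), with exact conditional binomial intervals at the 95% level. They cover counting error only, since reads without molecular identifiers are not independent molecules. Where the male library had no read, the exact lower bound is given in place of a ratio. Medians over peaks carry order-statistic intervals. Enrichment is density in the peak over density 1 to 5 kb either side, with an interval from 2000 bootstrap draws of peaks, and control positions lay 20 kb to either side of each peak. Windows of 500 bp were compared after drawing as many female as male reads with a fixed seed, with at least 20 reads in the higher library and a 4-fold difference. Sites were called in a library against its own surroundings as 500 bp windows moved by 250 bp with at least 15 distinct reads and 5-fold the density within 5 kb. This rule and its thresholds were chosen after the data were seen, and 3 settings were tried, with 521, 1710 and 283 sites in the thinned female library and 107, 1470 and 73 in the male library. The settings were 15 reads and 5-fold, 10 reads and 4-fold, and 20 reads and 5-fold.

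Since no genome sequence of the mm9 build was used here, sequence was rebuilt as the majority base of the reads of female part B. Of the read bases at positions covered by at least 2 reads, 99.8% were the majority base. This source of sequence was chosen after the data were seen, as the planned motif comparison called for a genome of the build. Motif hits on either strand were counted per kb of known sequence within 100 bp of the peak midpoint and from 900 to 1100 bp away. Intervals came from 1000 bootstrap draws of peaks, except those of the ranked short sequences, which are exact intervals on hit counts. McNemar's test, planned for this comparison, was not run because the known sequence differs between a peak and its flanks. Ratios were also computed for up to 100 shuffled orders of each motif's letters, against flanks 500 to 1500 bp away.

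The peaks named in the text were set by a rule written before the data were examined. It took the 10 peaks with the highest score, the 10 with the highest lower bound of the ratio among those with at least 20 female reads, the 5 with the lowest upper bound, and the 10 windows with the highest male to female lower bound. It also named genes near peaks. The gene table at hand is of the GRCm38 assembly, so positions of peaks relative to genes and lists of genes near peaks were not analysed here, and no gene is named from a position.

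Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The methods were tested on simulated data. With counts drawn for the 1962 peaks, the interval covered a 6-fold ratio in 99.5% of 200 peaks and a ratio of 1 in 98.9% of 1762, and lay above 1 in 83.5% of the 6-fold peaks. In simulated data with an even background and no pile-ups, the window rule recovered all of 200 planted windows in each direction. There the site rule recovered all of 200 planted sites of 30 reads, against its minimum of 15, and the rules made 0 other calls. The windows too were planted with mean counts above their minimum, so recovery was largely set in advance and weaker signal was not simulated. Background reads in the site simulation were sparser on chromosomes other than 1, so the lack of other calls there says little. The simulation does not test how often pile-ups in the deposited reads are called. Of bases rebuilt from simulated reads of even coverage, 99.98% were right. Alternatives changed the treatment of repeated reads, scaling, depth, read placement, file parts, flanks, window width, thresholds, the motif window and the part of the list used.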

Results

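CUX2 binding was mapped in mouse liver by chromatin immunoprecipitation and sequencing, with 1 sample from male and 1 sample from female CD-1 mice aged 8 weeks. CUX2 is a cut-family homeodomain transcription factor, known from mouse liver as more abundant in females. CD-1 is an outbred mouse stock. The design asks where CUX2 is bound in female liver and where it is bound in male liver. The female library held 33684680 reads on chromosomes 1 to 19 and X, and the male library held 8044595. The female file joined 4 parts of 15346301, 10782215, 3283326 and 4272838 reads, named here female parts A to D, and the male file joined parts A and B of 3919084 and 4125511 reads. The parts belong to 1 sample per sex, and the labels do not say what they are or whether they are separate libraries. They were not treated as replicates, so no difference between the sexes has a replicate check and no p-value is given. Ratios between the libraries carry exact intervals that cover counting error only and compare these libraries, not the sexes.

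The sex labels were checked on chromosome X. It took 4.80% of the female reads (95% exact Clopper-Pearson interval 4.79% to 4.80%) and 2.67% of the male reads (2.66% to 2.69%). Reads per base on X relative to the autosomes were 0.747 in the female and 0.408 in the male library. The share was 4.58% to 5.08% in the 4 female parts and 2.65% and 2.70% in the male parts, so all parts matched the sex of their library. Reads repeated at a position and strand made up 15.4% of the female and 16.6% of the male reads. Part B starts were not moved for these shares, so most minus-strand repeats between female parts A and B were not counted in the female share.

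The authors' deposited table lists 1962 peaks in which female reads exceeded male reads. It holds 1 direction of the comparison, with the female reads as the immunoprecipitate and the male reads as the control. The peaks had a median length of 604 bp (258 to 2196 bp) and covered 1221 kb of the mm9 genome. In the authors' deposited table the score, the caller's p-value on a negative log scale multiplied by 10, ran from 50.04 to 2216.96 with a median of 79.6. The fold enrichment in the same authors' deposited table ran from 2.99 to 63.18 with a median of 7.78. The authors' deposited false discovery rate had a median of 2.87% and a highest value of 20%. The peak peak_1037, among the 10 highest scores, had that highest value. It stood at rank 5 by score, where 20% implies only 1 region called with the libraries swapped. At the lowest score the rate was 2.34%, which implies 46 such regions. Peaks lay on all 20 chromosomes read, at 0.743 per Mb. Chromosome 19 was the densest at 1.45 per Mb (95% Poisson interval 1.17 to 1.79) and chromosome X the sparsest at 0.246 (0.177 to 0.334), with 41 peaks, 2.09% of the list on 6.31% of the sequence. Female reads per base on X were 0.747 times those on the autosomes, and the peak densities were not adjusted for read density. Of the peaks, 803 (40.9%) had another peak within 100 kb, against a median of 290 and a highest value of 388 in 1000 random placements on the same chromosomes. The placements were uniform and took no account of where reads can map or peaks can be called. Peaks close together also count as neighbours, and merging within 1 kb left 1922. The excess is therefore not shown to be a trait of CUX2 binding.

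Female read density over the listed peaks was several times the male density. With reads scaled to library size (RPM), the median female to male ratio over the 1962 peaks was 6.29 (95% interval of the median 5.97 to 6.69). The pooled ratio was 5.88 (5.72 to 6.05), from 128380 female and 5214 male reads. The interval lay above 1 in 1621 peaks (82.6%), above 2 in 553 and below 1 in 0, and 374 peaks held no male read. The peaks were selected by the authors for this difference on these same libraries, so the counts are not independent evidence of its direction. The pooled ratio was 8.22 (7.84 to 8.61) in the 490 peaks with the highest scores and 4.53 (4.23 to 4.85) in the 491 with the lowest. In the 41 peaks on X, of which 20 held no male read, it was 8.90 (6.95 to 11.6) and the median was 19.3 with a lower bound of 9.08, on a chromosome whose share of all reads was itself 4.80% in the female and 2.67% in the male library. The male counts were low, with a median of 2 reads per peak against 45 in the female library, and this limits the precision of each single ratio. The pooled ratio moved between file parts, from 4.41 for female part D against male part B to 10.8 for female part C against male part A.

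**Figure D1:**
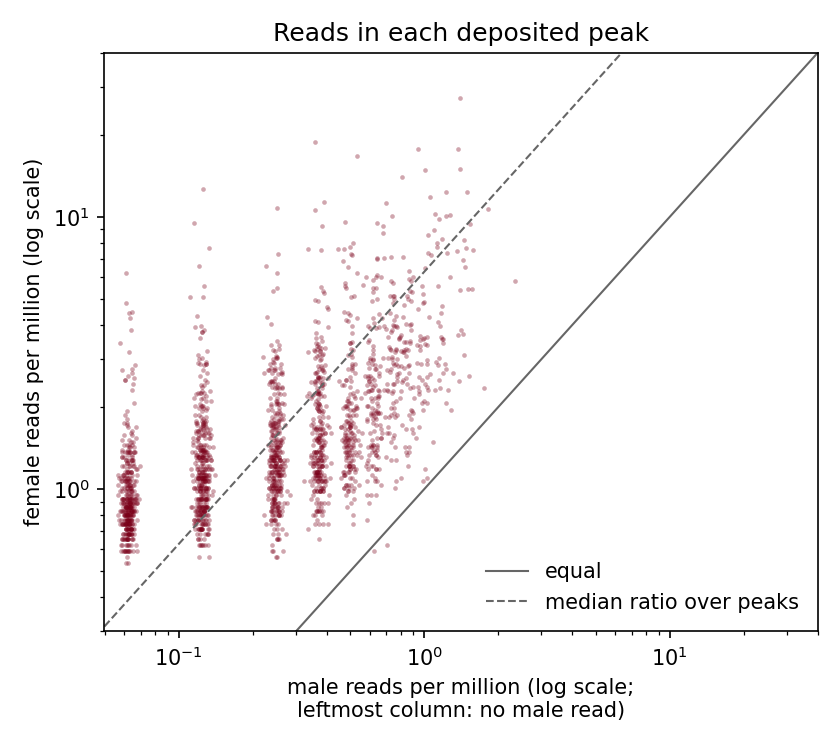
Female against male RPM in each of the 1962 deposited peaks, both on log axes, 1 point per peak with a small random horizontal offset for visibility. The 374 peaks with no male read stand in the leftmost column, and 2 peaks lie below the solid line of equal density, with the median ratio of 6.29 dashed.

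Among 20 peaks named by score or by the bounds of the ratio, ratios ran from 0.836 to 102, with 2 peaks without a male read given as lower bounds. The peak with the highest score, peak_1457 on chromosome 5 (122466481 to 122467693, mm9), held 470 female and 6 male reads, a ratio of 18.7 (8.53 to 51.2). Its density was 14.97 times that of its flanks in the female library and 1.01 times in the male library. The peak on chromosome 11 at 60692762 to 60693649 (peak_305) had the highest lower bound, with 427 female reads and 1 male read, a ratio of 102 (18.2 to 4037). On the same chromosome, peak_270 (18920276 to 18921094) held 636 female and 3 male reads, a ratio of 50.6 (17.2 to 246). Among the 10 peaks with the highest scores, on 8 chromosomes, ratios ran from 11.9 to 102. Of these, 5 also stood among the 10 peaks with the highest lower bounds. That group included 2 peaks with no male read, peak_637 on chromosome 15 (41672415 to 41673167), with 210 female reads and an exact lower bound of 13.5, and peak_1640 on chromosome 6 (148263942 to 148264630), with 162 female reads and an exact lower bound of 10.4. With 1 read per position and strand, the ratio of peak_1317 on chromosome 4 (117899703 to 117900675) moved from 19.996 (11.1 to 40.2) to 8.38. At the other end, the 5 peaks with the lowest upper bounds had ratios from 0.836 to 1.35 and scores in the authors' deposited table from 50.79 to 63.06. In those 5 peaks the male density was also above its flanks, by 3.59-fold to 5.91-fold. They were named for low female to male ratios, so male density above the flanks was largely set by the choice. Each held 6 to 14 male reads, and in peak_258 male part A held 13 of the 14. With 1 read per position and strand the 5 ratios ran from 1.27 to 1.52.

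Within each library, density in the peaks was compared with the flanks 1 to 5 kb either side, which removes the scaling between libraries. The female library was enriched at nearly every listed peak and the male library at about the rate of control positions. The pooled female enrichment was 5.58-fold (bootstrap interval over peaks 5.35 to 5.80), the median 4.41 (4.31 to 4.54), and 1918 peaks (97.8%) reached 2-fold, against 5.63% of positions 20 kb away. The pooled male enrichment was 1.05-fold (1.01 to 1.08), the median 0.866 (0.807 to 0.917), and 282 peaks (14.4%) reached 2-fold, against 15.5% of those positions. The male median at those positions was 0.809. Each of the female parts was enriched, at 5.49, 5.06, 8.55 and 4.53-fold, and male parts A and B stood at 0.984 (0.928 to 1.04) and 1.10 (1.06 to 1.15). In the 490 peaks with the highest scores the male enrichment was 1.21-fold (1.13 to 1.29) beside 8.77-fold (8.23 to 9.30) in the female library. In the 491 with the lowest scores it was 0.836-fold (0.767 to 0.913), below its own flanks. The peaks were called with the male reads as the control, so low male density in them was in part set in advance.

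The male value was higher at sites chosen another way, a comparison added after the data were seen that also changed the regions to 500 bp windows and the counting. At 926 sites called from female part B alone, with no male read used and 1 read per position counted, the median male enrichment was 1.78-fold (1.66 to 1.85) and the median in female parts C and D was 13.1 and 6.67-fold. At the 609 of these sites that overlapped the list, the male median was 1.33-fold (1.23 to 1.45). At the 317 outside the list it was 3.66-fold (3.20 to 4.0), while the female median there was 7.21-fold (6.74 to 7.81). That female value counts the part B reads used to call the sites, and female parts C and D stood at 10.3 and 6.40-fold there. The list was called against the male reads, so splitting the sites by it uses male reads. Higher male density outside the list was therefore in part set in advance.

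**Figure D2:**
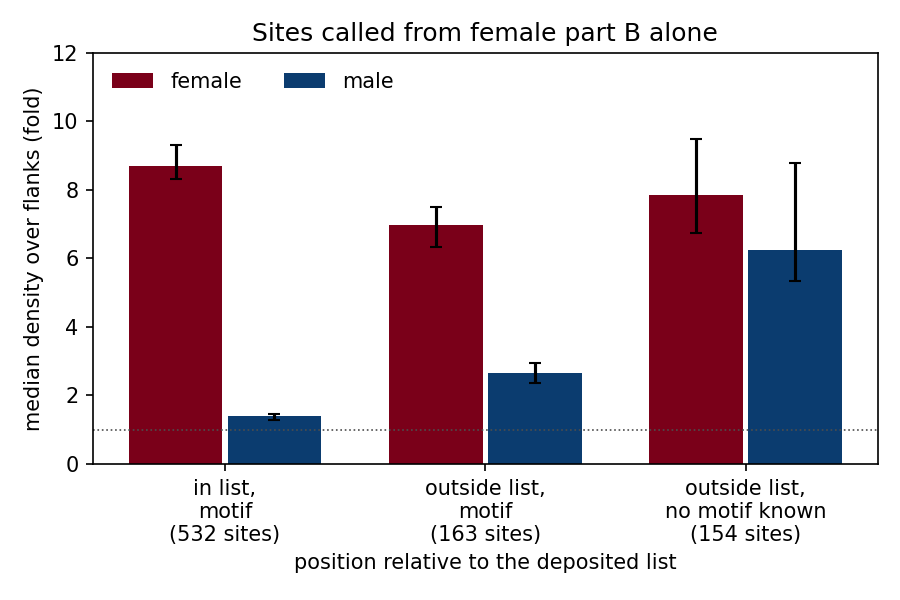
Median density over flanks, in fold, in the female and male libraries at sites called from female part B alone, by overlap with the deposited list and by presence of the ATYGAT motif in known sequence. The female values count the part B reads used to call the sites, and the list was itself called against the male reads. Error bars are 95% intervals of the median and the dotted line is 1-fold, with male medians of 1.402 in 532 listed sites with the motif, 2.67 in 163 others with it and 6.26 in 154 others without it.

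**Figure D3:**
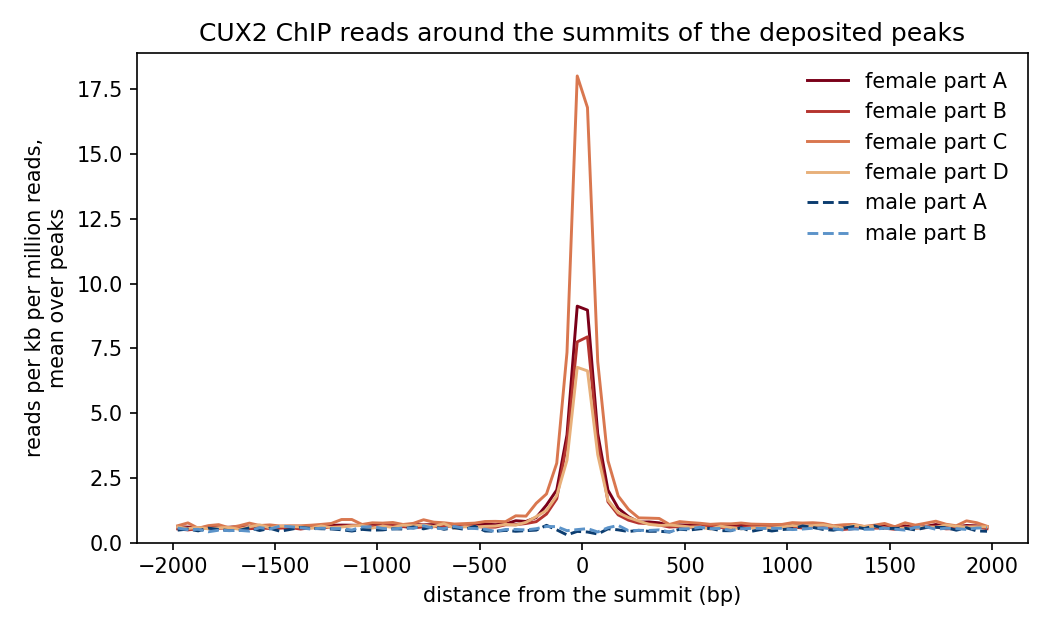
Mean density of reads around the summits of the 1962 deposited peaks, in RPM per kb for each file part, in 50 bp bins to 2000 bp either side. Solid lines are the 4 female parts, which reach 6.77 to 18.0 in the bin just before the summit, and dashed lines are the male parts, at 0.432 and 0.502 in that bin.

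**Figure D4:**
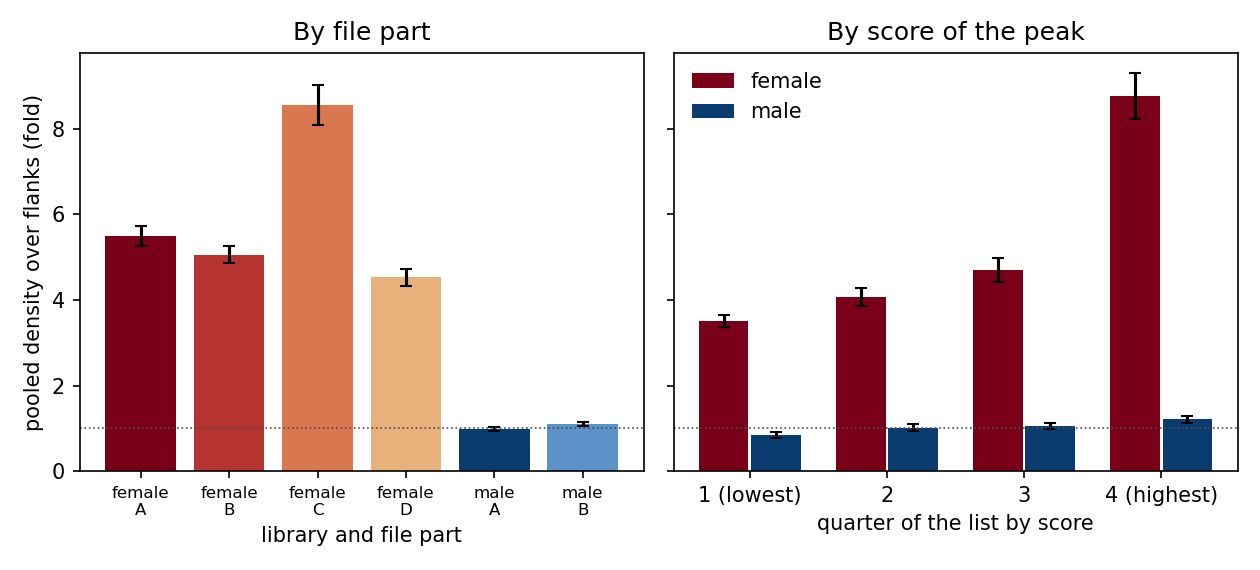
Pooled density in the deposited peaks over their flanks 1 to 5 kb away, in fold, by file part (left) and by score in groups of 490 or 491 peaks (right). With 95% bootstrap intervals over peaks as error bars and 1-fold dotted, female bars lie between 3.51 and 8.77-fold, and male bars between 0.836 and 1.21-fold.

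The mirror comparison asked for windows with higher male density. With the female reads thinned to the male total, 59 windows of 500 bp held at least 20 male reads and at least 4 times as many male as female reads, and 341 windows met the same rule in the female direction. Of the female-higher windows, 306 (89.7%) overlapped the deposited peaks, and of the male-higher windows 0, which the calling of the list as female over male on these reads largely set in advance. Chromosome X held 32 of the 59 male-higher windows and 3 of the 341 female-higher ones. No line names chromosome Y, and the cause of this X share was not tested. The motifs were not searched at these windows, so they are not shown to be CUX2 sites. The window with the highest lower bound lay on chromosome 18 (85885501 to 85886000) and held 220 male and 3 thinned female reads, a ratio of 73.3 (24.8 to 358). It reached 27.0 and 27.6 RPM in male parts A and B, against at most 0.702 in the female parts. Among the 10 windows named by that bound, 5 lay on X, 3 of them between 121307001 and 121309000, with male to female ratios of 31.2 (13.1 to 97.4), 27.5 (7.26 to 233) and 50.5 (13.6 to 423). In 54 of the 59 windows each male part held at least 25% of the male reads. With 1 read per position and strand the counts were 58 male-higher and 179 female-higher windows, and the male-higher count was 138 with windows of 1000 bp and 98 at 2-fold. The order of the directions depended on the read minimum. At 10 reads the rule took 5303 male-higher and 1790 female-higher windows, and with 1 read per position and strand at that minimum 577 and 834.

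Sequence around the peaks was searched for 9 motifs, in sequence rebuilt from the reads themselves. The cut-homeodomain core ATYGAT (Y is C or T), the form bound by CUX proteins and by HNF6, was concentrated at the peaks. It occurred 7.58 times per kb of known sequence within 100 bp of the peak midpoint and 0.758 times per kb in windows of the same width 1 kb away. This is a ratio of 9.999 (bootstrap interval over peaks 7.99 to 13.2), with at least 1 hit in 979 peaks (49.9%). The longer form ATCAATC had a ratio of 19.4 (11.6 to 40.7) with a hit in 282 peaks, and the degenerate form RTCRATW a ratio of 6.73 (5.34 to 8.96) with a hit in 776. Against flanks 500 to 1500 bp away, each of these 3 forms stood above all of 100 shuffled orders of its letters, though the highest shuffled ratio was 19.1 for ATCAATC, beside 21.1 for the motif itself. Leaving out 130 peaks at tandem ATCA repeats, chosen after the data were seen, moved the ATCAATC ratio to 5.05 (2.94 to 10.2). The core's ratio to flanks 500 to 1500 bp away was 13.8 (11.2 to 17.5) in the 491 highest-scoring peaks and 8.10 (5.91 to 11.3) in the 491 lowest-scoring, with overlapping intervals.

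The point ratios of the other motifs were lower than that of the core. The interval for C/EBP includes the core's 9.999, and differences between motifs were not tested. The FOXA motif TRTTTAC, of forkhead factors that open liver chromatin, had a ratio of 1.53 (1.15 to 2.23). Against flanks 500 to 1500 bp away it was 1.60, which 7 of 100 shuffled orders reached. For C/EBP, leucine zipper factors of hepatocytes, the ratio was 3.49 (1.59 to 16.98) on 37 hits at the peaks and 5 in the flanks, and against the wider flanks it was 3.61, which 4 of 99 shuffled orders reached. STAT5, which carries the growth hormone signal that differs between the sexes, had a motif ratio of 1.18 (0.713 to 2.11), and against the wider flanks it was 1.35, which 27 of 100 shuffled orders reached. The AP-1 motif had a ratio of 1.88 (1.10 to 3.65), which was 1.35 (0.945 to 1.90) against flanks 500 to 1500 bp away, where 31 of 100 shuffled orders reached it. HNF4A and CTCF had 8 and 3 hits at the peaks, too few to set a ratio. Known sequence covered 67.8% of the bases within 100 bp of the midpoints and 17.9% of the flank windows, so shares of peaks with a hit are lower limits.

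**Figure D5:**
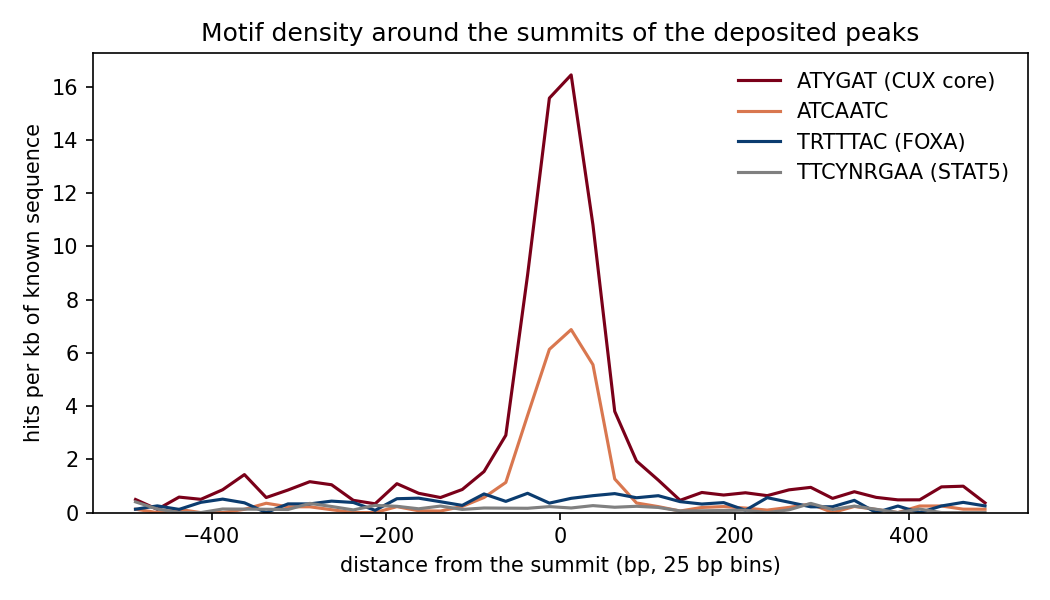
Density of 4 motifs around the summits of the deposited peaks, in hits per kb of known sequence in 25 bp bins to 500 bp either side. The ATYGAT core reaches 16.4 hits per kb in the bin after the summit and 0.365 in the last bin, and the FOXA and STAT5 lines stay near the bottom of the plot.

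Among the named peaks, the core was present within 100 bp of the summit at all 10 with the highest scores, while peak_1640 had no core there with 100% of the sequence known. At peak_1457, chromosome 5 from 122467117 to 122467177 read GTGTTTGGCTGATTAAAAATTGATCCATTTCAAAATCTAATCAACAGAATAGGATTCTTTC. At peak_270, chromosome 11 from 18920578 to 18920638 read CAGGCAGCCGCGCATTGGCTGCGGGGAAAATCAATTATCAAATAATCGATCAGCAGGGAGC, with 2 core hits within 100 bp. At peak_305, chromosome 11 from 60693201 to 60693261 read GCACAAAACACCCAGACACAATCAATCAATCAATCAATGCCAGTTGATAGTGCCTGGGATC, a tandem ATCA repeat with 4 core hits within 100 bp.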

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

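The tests of position sharing, of the ratio without part A and both tests of the tandem repeats were chosen after the results were seen.

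Read positions of female part A were found again in the other female parts, a signal outside the comparisons of the report. Of the distinct positions of parts B, C and D, 6.96%, 21.96% and 19.1% were also present in part A. Chance coincidence in dense regions is argued against by positions 50 bp away, since exact positions were shared at least 16.8 times as often, while the 10 pairs of parts without part A gave 1.47 to 2.31 times. A repeated sequencing of the same library molecules stays open as a hypothesis, would make the counting intervals too narrow, and no biological explanation was tested. Parts B, C and D shared at most 0.558% of positions with each other, at 1.49 to 2.20 times the rate 50 bp away. Their pairs with male parts gave 1.47 to 2.31 times, so no sharing beyond that between the sexes was seen among them. Whether they are separate libraries was not tested. The pooled female to male ratio of parts B, C and D alone was 5.88, so including part A did not raise it. Sharing spread evenly over the genome would not move a ratio scaled by all reads. With 1 read per position and strand, which also removes other repeats, the pooled ratio was 5.12.

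Tandem ATCA repeats of at least 14 bp lay within 100 bp of the summit in 130 peaks (6.63%), against at most 2 peaks for 4 other repeat units, in sequence the comparisons of the report did not plan to use. A pile-up of reads from elsewhere in the genome, shared by both libraries, is argued against by 81 sites with such a repeat called from female part B alone, with no male read used, where the median male enrichment was 1.45-fold (1.14 to 1.60) beside 12.6-fold (10.7 to 15.2) and 8.0-fold (6.19 to 9.6) in female parts C and D, which were not used to call them, although 19 of them reached 2-fold in the male and the 15 outside the list, with a male median of 1.85-fold (1.14 to 2.67), leave it open for their part. Arrays of the bound motif may account for these peaks, since each repeat holds the core several times. The pooled female enrichment there was 7.08-fold (6.23 to 7.95), with intervals overlapping those of 6.19-fold (5.79 to 6.67) in 587 peaks with exactly 1 core hit and 7.75-fold (7.20 to 8.37) in 345 with more than 1. That is a hypothesis found and tested on the same data, in classes that depend on how much sequence the female reads made known.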

How the results depend on the processing

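Alternatives on part B sites, leaving out part A, the header's fragment length, tandem repeats, motif flanks, motif centring, X shares, pile-ups and 1 read per position with 10 reads were chosen after seeing the data. No paired analysis was possible because each sex has 1 sample. Alternatives on gene positions (promoter width) and gene lists (distances, overlap, score) were not run, nor was one within runs read from read names, in place of which file parts were used. In 211 recomputations, 178 stayed within the interval or within 1.5 times the count, 32 moved and 1 changed side. Of 108 for 18 named peaks, 107 stayed within the interval. Those intervals were often wide, such as 18.2 to 4037 for peak_305. Without the named peaks and the STAT5, FOXA, C/EBP and AP-1 motifs, 51 of 83 stayed, 31 moved and 1 changed side. The cause was not tested for the values below. The higher-scoring peaks (981) had a median ratio of 7.05, a pooled ratio of 6.87 and 937 intervals above 1. With 1 read per position and strand the median ratio was 5.47, the pooled ratio 5.12, the female enrichment 4.197 (median) and 4.997 (pooled), and 179 windows were higher in female. The X shares were then 4.93% and 2.73%, with the part B starts not moved. Pooled ratios of female parts A, B, C and D were 6.27, 5.41, 10.8 and 4.98 against male part A, and 5.55, 4.79, 9.54 and 4.41 against male part B. Flanks 5 to 10 kb away gave a female enrichment of 4.78 (median) and 6.11 (pooled) and a male pooled value of 1.10. At sites called from female part B alone the median was 8.11 in the female library, part B included, and, above 1 in place of below it, 1.78 in the male. Positions 20 kb from the deposited peaks had a male median of 0.809, so a male median below 1 also occurred away from the peaks. Male-higher windows numbered 138 at 1000 bp, 98 at 2-fold and 5303 at 10 reads, with 1790 female-higher, and 577 and 834 at 10 reads with 1 read per position. Without tandem repeat peaks the ATYGAT ratio was 7.05 and the ATCAATC ratio 5.05. Low male depth limits every single-peak ratio.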

Other observations

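The test on flank ratios, the sites called within a library, the core forms and the ranking of short sequences were chosen after the data were seen.

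Both forms of the core were concentrated at the peaks. Within 100 bp of the midpoint, ATCGAT had 198 hits, 15.3 times (10.9 to 23.7) its density 500 to 1500 bp away. ATTGAT had 1683 hits and a ratio of 10.5 (9.22 to 12.2). Among all 2080 sequences of 6 bases ranked by the lower bound of their ratio within 50 bp of the summit, with no motif given in advance, ATCGAT came first at 27.4 (18.6 to 41.8) and ATCAAT next at 18.3 (16.4 to 20.4). Among 32896 sequences of 8 bases, ATTGATTG led with 676 hits at the summits and 46 in the flanks, a ratio of 63.7 (47.2 to 87.9). It and ATCAAT also occur in the tandem ATCA repeats found at 130 peaks, which were not left out of these rankings. The intervals in the rankings are exact intervals on hit counts and not bootstrap draws of peaks. Hits in the same peak, such as overlapping hits in a repeat, are not independent, so these intervals are likely too narrow.

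Of the 107 sites called in the male library alone, 0 overlapped a deposited peak, and 7 of 1470 did at 10 reads and 4-fold. The list was called as female over male on these reads, so a low overlap was largely set in advance. In the thinned female library, 48 called sites overlapped a male-called site. The female library was enriched 9.14-fold (5.82 to 13.4) at these male-called sites. The segment of chromosome 2 from 98500001 to 98520000 held 2.07% of the female and 2.80% of the male reads.

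The male library was near its local background at the deposited peaks. A copy number or mappability difference spanning several kb around the peaks is argued against by the flanks 1 to 5 kb away. There the median female to male ratio was 1.07 (1.06 to 1.10). A difference confined to the peak itself would leave the flanks unchanged and was not tested. The choice of peaks on these libraries is argued against as the whole cause by sites called from female part B alone. At those sites the male median of 1.78 stayed below 50% of the medians in female parts C and D. Sites enriched in both libraries may have been left out of the list, since part B sites outside it held the core at 5.64 times (4.24 to 7.98) the density of their flanks, though the ratio fell as male enrichment rose, from 9.90 (5.78 to 22.8) in the 75 with a male enrichment below 2-fold to 4.50 (3.27 to 6.80) in the 242 at 2-fold or more and 2.58 (1.62 to 4.38) in the 144 at 4-fold or more, while listed sites at 2-fold or more in the male (172) kept 8.85 (6.38 to 13.5), beside 9.37 (7.82 to 11.4) in all 609 listed sites. Among part B sites with a core, the median female to male ratio was 7.39 (6.66 to 7.85) in 532 listed sites, which were selected for low male reads. In the 163 others it was 2.92 (2.66 to 3.13), and the pooled ratio was 1.33 (1.26 to 1.396) with 56.2% of the male reads in 5 sites. In 231 sites with no known core the median was 1.96 (1.56 to 2.28) and the pooled ratio 0.907 (0.877 to 0.938). All these sites were called for high density in female part B, and its reads count in the female values. Ratios above 1 were therefore in part set in advance. A weaker immunoprecipitation in the male livers cannot be told apart from less binding: the core ratio was 1.34 (0.401 to 3.48) at male-called sites and 7.80 (6.37 to 9.87) at sites called in the thinned female library, but only 37.3% of the sequence was known at the former, against 64.8%, and no input library was compared, and a difference between the sexes in CUX2 binding stays open and untested.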
